A study of Mus musculus with 6 samples.

How the data were processed

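The series holds 6 RNA sequencing libraries of mouse gastrocnemius at 3 months of age, 3 labelled WT and 3 labelled as a muscle-specific Hnrnpu knockout (mKO). Per the labels' protocols, frozen muscle was extracted with Trizol and libraries were made with the NEBNext Ultra RNA kit. The kit as named does not mark strand, and the labels do not give the enrichment step. The deposited values are raw counts per gene, 1 table per library, in whole numbers that sum to different totals. Per the submitters' processing notes the tools were Trimmomatic 0.36, STAR 2.5.2b and featureCounts of Subread 1.5.2, with the GRCm38 build. Per the file headers, counts were summed over the exons listed for each Ensembl gene. Strand setting, counting of pairs and treatment of reads that map to several places are not given in the sources used here. Counts of overlapping genes, antisense genes and near-identical copies are therefore uncertain, and genes of multigene families and mitochondrial genes with nuclear copies can lose or exchange reads.

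Of 49315 genes in the tables, 48970 matched a symbol by gene identifier; gene classes and coordinates came from the GENCODE annotation of the same build. Of 686 listed symbols, Ctgf was matched through its newer name Ccn2 and Ahsp was not matched. Groups were taken from the sample titles. Totals ranged from 32108684 to 42344238 counts. Replicates of a group differed beyond sampling noise, with chi-square per degree of freedom from 20.9 to 57.7 over genes with at least 20 counts in the pair, so no library was a copy of another. All libraries had counts of the Y-linked gene Ddx3y (5171 to 7540) and at most 13 counts of Xist.

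The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the default expression filter by group (16650 genes kept) and Benjamini-Hochberg adjustment at 0.05. Every adjusted p of a single gene comes from it unless another tool is named. Group was the only term of the model. CPM values use the TMM-scaled library size unless said otherwise and are given as mean ± SD of 3 libraries. Fold changes are mKO over WT from the fitted model, with the standard error (SE) of the log2 value. For genes with 1 to 3 counts in a group the ratio of summed counts per scaled library size is given with an exact binomial 95% counting interval. With 0 counts the ratio is taken against a floor of 3 counts over the group and given with the lower limit of that interval. Intervals and floors cover counting error only. The biological coefficient of variation was 16.1%, and the smallest called fold was 1.21.

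The steps were tested on simulated data with the real genes, WT means and library sizes, in which 200 of 16650 genes were changed. They recovered 82% of 100 genes changed 2-fold and 40% of 100 changed 1.5-fold. The real comparison called 6166 genes, and the adjusted threshold loosens as more genes change. These shares are therefore not recovery rates of the real comparison. Of 127 calls, 5 were false (3.94%), and no unchanged list was called. Genes were simulated independently, whereas the estimated correlation in the data reached 0.69 for the macrophage list. The simulation therefore does not check the list test for correlated genes.

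Gene lists were fixed before the data were examined, 41 in all. They cover fibre types, development, denervation, the neuromuscular junction, stress pathways, growth and atrophy, metabolism, membrane and sarcomere structure, the clock, RNA-binding proteins, proliferation, matrix, immunity and 10 other cell types. Each list with at least 5 tested members was tested with camera of limma 3.58.1, a two-sided competitive test with a preset correlation between genes of 0.01, adjusted over 41 lists. Camera called 21 lists, 12 higher and 9 lower, of which 8 were also called with an estimated correlation. Those 8 are the developmental, denervation, integrated stress, fast-fibre, mitochondrially encoded, proliferation, matrix and triad lists. Some genes stand in more than 1 list, such as Chrng, Ncam1 and Ankrd1.

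Genes were named by a rule fixed at the same time. It takes Hnrnpu, the 10 largest rises and 10 largest falls with mean CPM of at least 1, no overlap of groups and a symbol that is not a predicted name, up to 4 members of each list by lowest p, up to 5 changed genes within 10 Mb of Hnrnpu by size, and the 5 lowest p in each direction. Of the genes the rule takes, 3 list members are not reported here. Predicted names made up 751 of the changed genes and were mostly counted only. Exceptions are 2310065F04Rik and Gm38251, which other parts of the rule take, and B230369F24Rik, chosen after its value was seen. Genes named outside the rule are marked as chosen after their values were seen.

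Alternatives were DESeq2 1.42.0, limma-voom, other scaling factors, other filters, robust dispersion, other thresholds, tests without the mitochondrial and 10 most abundant genes, a fit with the replicate number as a block, leaving out each library, and protein-coding genes alone, the last added after seeing the data. For lists they were fry, which tests a list against no change rather than against other genes, an estimated correlation, and leaving out shared genes. Exon usage was planned only for exon counts and was not run on these gene counts.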

Results

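RNA from the gastrocnemius, the large calf muscle, was profiled by sequencing in 3-month-old mice of a mixed C57BL/6 and 129 background. The series compares 3 WT libraries with 3 libraries labelled mKO, from mice in which Hnrnpu was knocked out in muscle only. Hnrnpu encodes a nuclear RNA-binding protein, also called SAF-A, with roles in chromatin organisation and splicing. The question named in the series is how this protein controls gene expression and splicing in skeletal muscle. Gene counts address the first part, and splicing was not analysed here. The total counts of WT replicates 1 to 3 were 34871043, 38414635 and 42344238, and those of mKO replicates 1 to 3 were 37838635, 38095211 and 32108684. Log-scale expression correlated at 0.978 to 0.985 within a group and at 0.944 to 0.947 between groups. The first principal component held 66.7% of the variance and separated the labels. The replicates are numbered in the labels without naming the animals, so p-values measure the spread between these libraries.

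Hnrnpu itself was only slightly lower in the mKO-labelled libraries, and this difference depended on how the libraries were scaled. The gene (ENSMUSG00000039630) lies on the minus strand of chromosome 1 from 178321108 to 178337797 in GRCm38, and its count sums reads over all listed exons. With TMM scaling it had 233, 235 and 247 CPM in WT replicates 1 to 3, a mean of 239 ± 7.59 (SD, n = 3). The mKO-labelled replicates 1 to 3 had 209, 210 and 205 CPM, a mean of 208 ± 2.92 (SD, n = 3), which is 87.2% of WT. The log2 fold change was -0.20 (SE 0.10, edgeR adjusted p = 0.147). The 2 groups did not overlap, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries can give. With CPM computed from library totals, the direction turned: WT had 203 ± 5.08 and mKO-labelled libraries 244 ± 7.22 CPM (SD, n = 3), a log2 change of 0.27 with edgeR adjusted p = 0.0402. A count over the whole gene does not check the labels where only some exons are deleted, and the deleted exons are not given in the sources used here. All directions below are therefore those of the libraries as labelled.

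**Figure D1:**
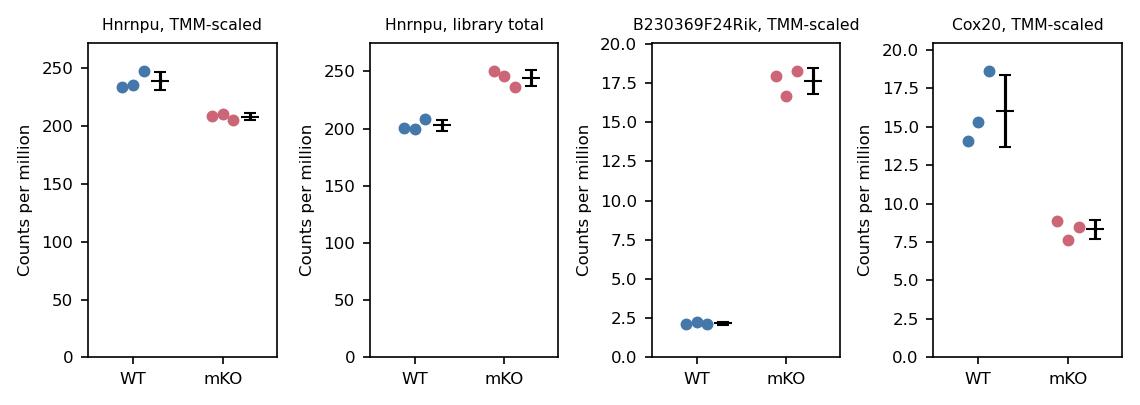
CPM of Hnrnpu with TMM scaling and per library total, and of its neighbours B230369F24Rik and Cox20 with TMM scaling. Points are single libraries, bars show mean and SD of 3 libraries; Hnrnpu was slightly below WT with TMM scaling and above it with library totals.

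The genes next to Hnrnpu changed more than Hnrnpu did; both were chosen after their values were seen. B230369F24Rik, a noncoding gene on the same strand that starts 2559 bp beyond the 3′ end of Hnrnpu (178313328 to 178318549), rose from 2.17 ± 0.0675 to 17.6 ± 0.842 CPM (log2 3.02, SE 0.15, edgeR adjusted p = 5.89e-08). Cox20, an assembly factor for cytochrome c oxidase, lies on the opposite strand (178319130 to 178322693) and overlaps the 3′ end of Hnrnpu. It fell from 16 ± 2.34 to 8.31 ± 0.623 CPM (log2 -0.95, SE 0.14, edgeR adjusted p = 0.00027). Since the library kit as named does not mark strand, reads in the overlap could not be assigned to 1 gene by strand, whatever the counting setting.

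The mKO-labelled muscle differed from WT in a large part of the expressed transcriptome. Lists of embryonic and denervated muscle, the integrated stress response, cell division and matrix were higher, and those of fast fibres and mitochondrially encoded genes lower, also with an estimated correlation. Macrophage genes were higher, and fatty acid oxidation, respiratory chain, glycolysis and endothelial genes lower, with calls lost with adjusted p = 0.187, 0.228, 0.249, 0.119 and 0.249 with an estimated correlation. Of 16650 genes tested, 6166 changed (37.0%), 3022 of them higher and 3144 lower. At least 2-fold changes numbered 2359, of which 1461 were higher and 898 lower. Counted without a test, 8216 genes (49.3%) had no overlap between groups, against a chance share of 10% for 3 against 3 libraries. The split of directions rested on scaling. With library totals in place of TMM factors, the median log2 fold change of all genes moved up by 0.465, and 9283 genes were called, 8159 higher and 1124 lower (87.9% higher against 49.0%). Fold changes below are relative to the TMM-scaled bulk of genes.

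The libraries also differed in the share of the most abundant transcripts. The 10 most abundant genes took 34.6 to 35.8% of counts in WT libraries and 29.0 to 32.3% in mKO-labelled ones, and mitochondrially encoded genes took 5.60 to 5.95% against 3.46 to 3.63%. The share of Ttn by itself went the other way, with 14.5 to 14.9% in WT and 15.2 to 18.6% in mKO-labelled libraries. The small structural RNAs Rn7sk and Rpph1 took 2.09 to 2.42% against 2.58 to 3.22%, and protein-coding genes 95.03 to 95.07% against 93.5 to 94.0%. Between 21748 and 22416 genes had a count in WT libraries, and between 23651 and 24539 in mKO-labelled libraries.

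The largest rise with WT counts to measure it was Sln, which encodes sarcolipin, an inhibitor of the sarcoplasmic reticulum calcium pump: 1.12 ± 0.174 against 227 ± 66.8 CPM (SD, n = 3), 203-fold. Asns, which makes asparagine, rose from 1.35 ± 0.189 to 72.6 ± 14.8 CPM (53.6-fold). Myh3, the embryonic myosin heavy chain, rose from 4.08 ± 1.6 to 193 ± 21.7 CPM (47.7-fold), and Mthfd2, a mitochondrial folate enzyme, from 4.40 ± 0.168 to 129 ± 5.04 CPM (29.4-fold). Among genes near the floor, Olfr859 had 0 counts in WT and 358 in mKO-labelled libraries. The ratio was 92.4 against a floor of 3 counts over the group, and the exact 95% lower counting limit was 74.8. Chrng, the fetal acetylcholine receptor subunit, had 2 against 346 counts, a ratio of 134 (exact 95% counting interval 36.8 to 1110). Mymk, which encodes the fusion protein myomaker, had 3 against 359 counts, a ratio of 92.7 (31.5 to 451), and Klk1b22 3 against 313, a ratio of 80.8 (27.4 to 394). Gsdma (65.4-fold) and Dtl (30.6-fold) completed the 10 largest rises. Olfr859 and Klk1b22 belong to multigene families, so their counts are uncertain.

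The largest fall was that of Slc15a5, a member of a peptide transporter family, from 18 ± 3.49 to 0.113 ± 0.0479 CPM (log2 -7.30, 158-fold lower). Mss51, a muscle-enriched gene of mitochondrial metabolism, fell from 175 ± 50.2 to 2.27 ± 1.24 CPM (78.3-fold lower), and Cd27 was 39.6-fold lower. Next came Odf3l2 (18.9-fold), BC048679 (18.6-fold), the ATPase gene Atp13a5 (17.4-fold), the potassium channel genes Kcnf1 (16.4-fold) and Kcnab1 (15.2-fold), the transcriptional cofactor gene Dach2 (14.7-fold) and the antisense gene Irx3os (13.2-fold). Among the lowest p-values were also Runx1 (7.96-fold higher) and, lower, Ankrd23 (from 1565 to 164 CPM, 9.56-fold), a titin-binding stretch-response gene, and the noncoding RNA 2310065F04Rik, which lies between Myh3 and Myh1 on chromosome 11 (191 to 13.3 CPM, 14.4-fold). The edgeR adjusted p was between 2.38e-10 and 3.29e-05 for the genes of this and the preceding paragraph.

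**Figure D2:**
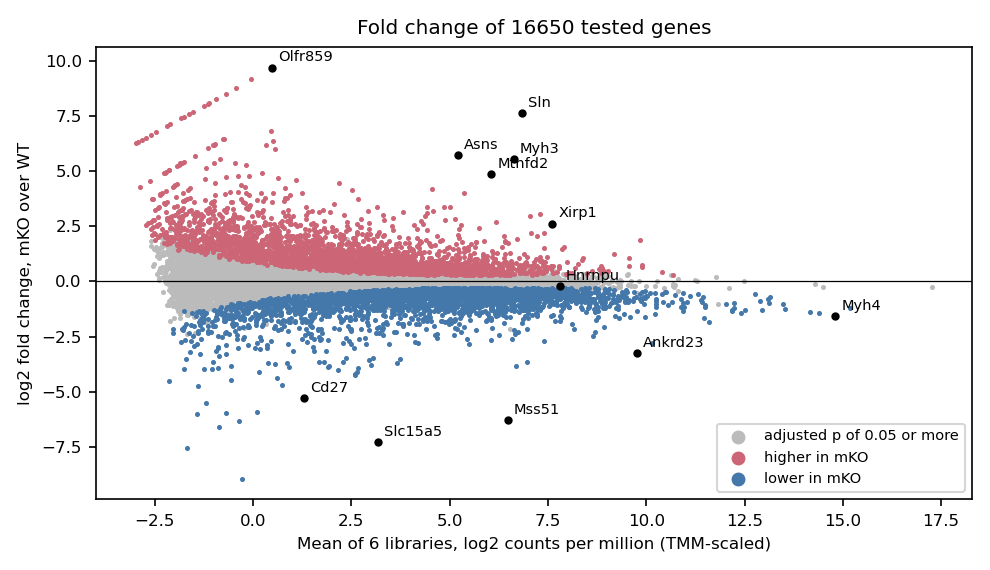
Log2 fold change, mKO over WT, against the log2 mean CPM of 6 libraries for 16650 tested genes, each point 1 gene, with TMM scaling. Coloured points have edgeR adjusted p under 0.05 (3022 higher, 3144 lower); with library totals the split was 8159 higher and 1124 lower, and fitted folds of genes with 0 counts in a group are no measure of size.

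Genes of immature and denervated muscle formed the most raised groups. Of 17 tested genes of developmental and regenerating fibres, 16 rose and none fell (17 adjusted over the list alone), with a median log2 change of 2.36. Beside Myh3 were Tnnt2, the cardiac and embryonic troponin T (2.83 to 25.4 CPM, log2 3.17), the adhesion molecule gene Ncam1 (5.01-fold) and the imprinted gene Peg3 (3.49-fold). Of 17 denervation response genes, 14 rose and 1 fell (the same counts adjusted over the list alone). Sln, Runx1 and Ncam1 rose, as did Ankrd1, a stress-response gene of the sarcomere (4.80 to 78.2 CPM, 16.4-fold), while Dach2 was the 1 that fell. The list sets no direction for its single members. Camera adjusted p was 8.04e-27 for the first list and 3.01e-22 for the second, and 0.0451 and 0.0406 with an estimated correlation. Of 13 neuromuscular junction genes, 6 rose and 1 fell (the same adjusted over the list alone), and 10 rose and 1 fell with library totals. Camera did not call the list (adjusted p = 0.0638, but 0.0491 without WT replicate 1, 0.0114 without WT replicate 2 and 0.0130 without a low-count filter), while the directional fry test gave 0.00756. Ache, which encodes acetylcholinesterase, rose (4.75 to 15 CPM), as did Gramd1b (log2 1.39) and Musk, the receptor kinase of the junction (1.63-fold), while Chrne, the adult receptor subunit that replaces Chrng, fell (7.51 to 4.02 CPM, log2 -0.90).

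Fast-fibre contractile genes fell almost as a block. Of 16 tested, 15 fell and none rose (16 adjusted over the list alone), and 14 fell with library totals. Myh4, the heavy chain of the fastest fibres, fell from 42746 ± 1327 to 14356 ± 2383 CPM (log2 -1.57, SE 0.14, edgeR adjusted p = 4.58e-06), Pvalb, which encodes the calcium buffer parvalbumin, from 7892 to 2960 CPM, Mylk2 from 508 to 196 CPM, and Tpm1 from 31382 to 11624 CPM. Myh1, singled out after its value was seen, did not pass (log2 -1.01, SE 0.39, edgeR adjusted p = 0.0592). The median log2 change was -1.10 (camera adjusted p = 4.34e-16, and 0.0361 with an estimated correlation). Slow-fibre genes were mixed: of 15, 6 rose and 2 fell (the same adjusted over the list alone). Casq2, the calsequestrin of slow and cardiac muscle, rose 4.65-fold, the stretch sensor gene Csrp3 2.88-fold and the slow troponin gene Tnnt1 3.82-fold, while the slow light chain gene Myl2 fell (log2 -1.27; DESeq2 adjusted p = 0.0679, not called). The call for the list was weak (camera adjusted p = 0.0471, lost with adjusted p = 0.449 with an estimated correlation and 0.0617 without genes of other lists), and it ended without WT replicate 2 (adjusted p = 0.0698), WT replicate 3 (0.109) or mKO replicate 2 (0.742). The directional fry test did not call it either (adjusted p = 0.111).

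Other fibre structures changed in both directions. Of 23 sarcomere scaffold and Z-disc genes, 7 rose and 6 fell (the same adjusted over the list alone; camera adjusted p = 0.0909, but 0.0351 without WT replicate 2, 0.0397 without mKO replicate 1, 0.0420 with the replicate number as a block and 0.0201 without a low-count filter). Without genes of other lists the camera adjusted p was 0.487, the directional fry test gave 0.0131, and with library totals 13 rose and 3 fell. Xirp1, an actin-binding protein gene of damaged sarcomeres, rose from 54.1 to 335 CPM, Ankrd1 rose, and Flnc, which encodes filamin C, rose from 394 to 1434 CPM, while the Z-disc gene Cmya5 fell from 6691 to 2902 CPM. Of 22 genes of excitation-contraction coupling and the triad, 11 fell and 1 rose (12 and 1 adjusted over the list alone). Stac3 (log2 -1.26) and Jph2 (log2 -1.18), which hold calcium channels and membranes of the triad in place, fell, as did Sypl2 (log2 -1.13) and Trdn (log2 -1.35). The list was called lower (camera adjusted p = 3.87e-05, and 0.0451 with an estimated correlation), and camera still put it lower relative to other genes with library totals, where its median was 0.10 against -0.36, with 6 higher and 7 lower. Of 18 dystrophin complex and membrane repair genes, 8 fell and 5 rose (the same adjusted over the list alone; camera adjusted p = 0.0656, but 0.0482 without WT replicate 3 and 0.0131 without a low-count filter). The directional fry test put the list lower (adjusted p = 0.000397). With library totals 9 of its members rose and 5 fell, and the median turned from -0.13 to 0.33. Capn3 (log2 -1.11), Ano5 (log2 -1.17) and Sgca (log2 -1.02), whose human counterparts underlie limb-girdle dystrophies, fell. Dysf of the same list, named after its value was seen, rose (log2 0.46).

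**Figure D3:**
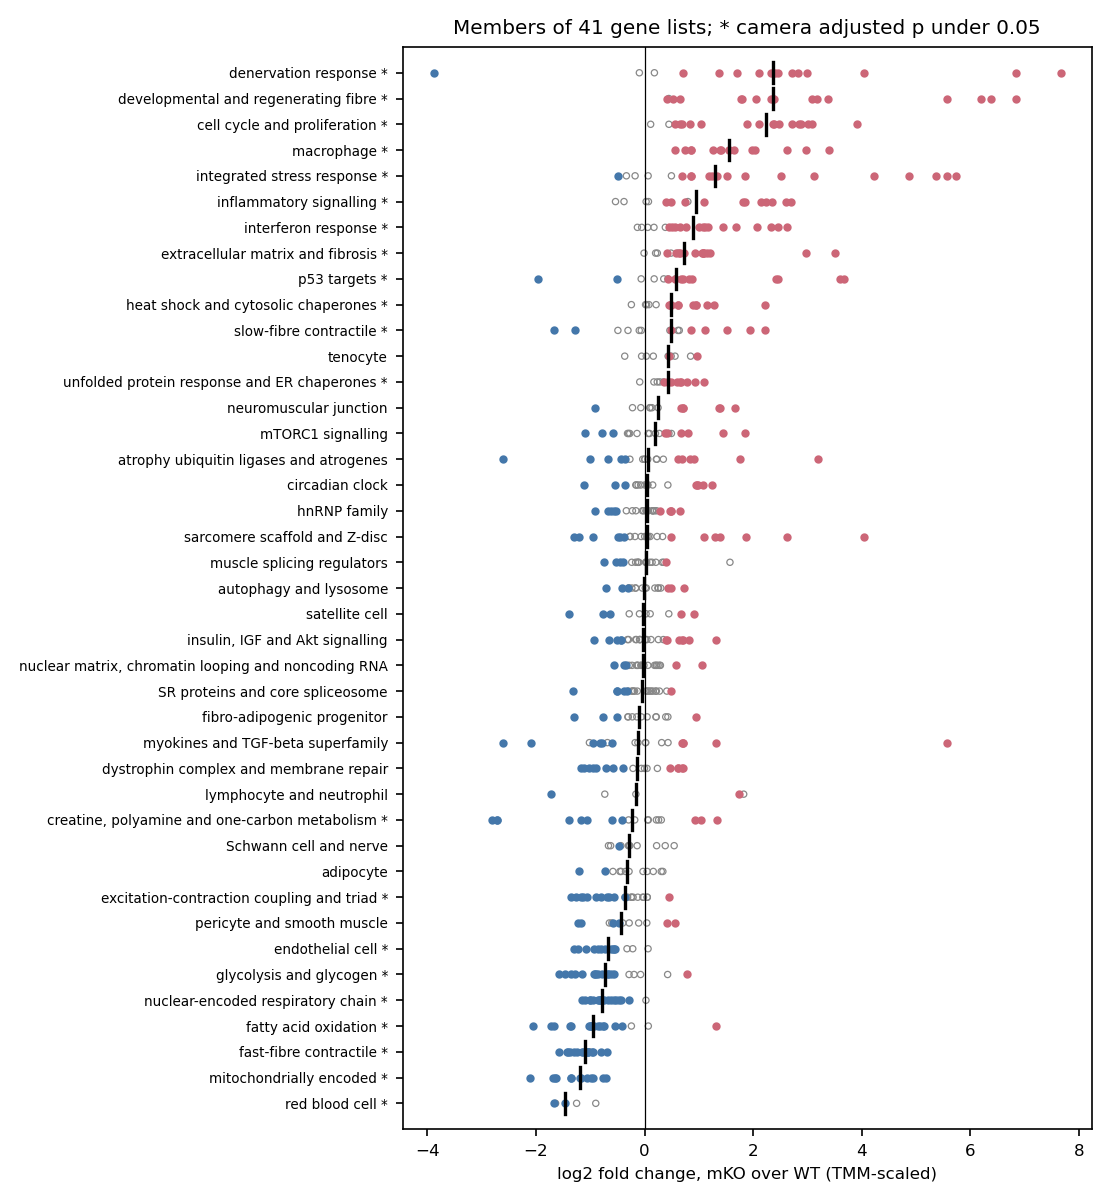
Log2 fold change, mKO over WT with TMM scaling, of each member of 41 gene lists, with filled points for edgeR adjusted p under 0.05, open points for other genes and black bars for medians. With library totals the median of all genes moves up by 0.465, and lists with small negative medians turn positive.

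Most listed genes of energy metabolism fell. All 13 mitochondrially encoded genes fell (also 13 adjusted over the list alone; 10 with library totals): mt-Co1 (chosen after its value was seen) from 51270 ± 2663 to 22533 ± 1110 CPM, mt-Nd1 from 4258 to 1365 CPM, mt-Nd2 from 1239 to 485 CPM and mt-Co3 from 110 to 25.6 CPM, counts that are uncertain because nuclear copies of mitochondrial DNA share reads with them. The median log2 change was -1.19 (camera adjusted p = 2.21e-14, and 0.0406 with an estimated correlation). Of 20 nuclear-encoded respiratory chain genes, 19 fell and none rose (19 adjusted over the list alone). Ndufs1 and Ndufa9 of complex I had log2 changes of -1.10 and -0.86, and Cox4i1 of complex IV fell from 649 to 325 CPM. Fatty acid oxidation lost 17 of 20 genes and gained 1 (the same adjusted over the list alone), among them Lpl, the lipase that releases fatty acids to muscle (787 to 190 CPM, 4.15-fold lower), Fabp3, their cytosolic carrier (3.16-fold lower), Acadm (log2 -1.37) and Cd36 (log2 -1.35). In glycolysis and glycogen, 14 of 20 fell and 1 rose (14 and 2 adjusted over the list alone). Phka1 of phosphorylase kinase (890 to 299 CPM), the muscle enolase gene Eno3 (6644 to 2587 CPM) and the aldolase gene Aldoa (log2 -1.29) fell. Camera adjusted p was 2.19e-08, 4.65e-10 and 2.05e-07 for these 3 lists, lost with adjusted p = 0.249, 0.228 and 0.119 with an estimated correlation, and with library totals 8, 11 and 9 of their members fell and 1, 2 and 3 rose.

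Polyamine and creatine genes moved in both directions. Of 18 listed genes, 8 fell and 3 rose (the same adjusted over the list alone), the rises being Sat1 (log2 0.93) and the creatine synthesis genes Gatm (1.33) and Gamt (1.04), named after their values were seen. Amd1, S-adenosylmethionine decarboxylase, fell from 1993 ± 459 to 286 ± 27.1 CPM (6.98-fold lower), its near-identical copy Amd2 from 9.42 to 1.43 CPM, with reads that the counting could split between the copies, and Smox, spermine oxidase, from 295 ± 12.6 to 44.7 ± 7.77 CPM (6.59-fold lower). Ckm, muscle creatine kinase, fell from 26416 to 10138 CPM. The list was called lower (camera adjusted p = 0.00215, but adjusted p = 0.158 with an estimated correlation), and camera still put it lower relative to other genes with library totals, where its median was 0.23 against -0.24, with 9 higher and 6 lower.

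The integrated stress response was raised. Of 20 genes, 15 rose and 1 fell (15 and 2 adjusted over the list alone; camera adjusted p = 8.22e-19, and 0.0361 with an estimated correlation). By lowest p, Mthfd2 and Asns led, followed by Psat1 of serine synthesis (2.36 ± 0.334 to 44.2 ± 15.8 CPM, 18.7-fold) and the transcription factor gene Atf3 (4.38 to 38.3 CPM, 8.71-fold). The fitted log2 changes of Fgf21 (5.56) and of Gdf15 (5.36, named after its value was seen) were larger than that of Mthfd2 (4.88). Smaller rises were found for 3 other stress lists. In the unfolded protein response 10 of 16 rose and none fell (13 adjusted over the list alone), with Herpud1 (log2 0.68), Xbp1 (0.78), Pdia3 (0.66) and Manf (0.94). Among heat shock and cytosolic chaperones 12 of 17 rose and none fell (the same adjusted over the list alone), with the small heat shock genes Hspb7 (log2 2.21) and Hspb3 (1.14), the cochaperone gene Bag3 (1.28) and Dnajb6 (0.49). Of p53 targets, 10 of 17 rose and 2 fell (the same adjusted over the list alone), with the cell cycle inhibitor gene Cdkn1a (log2 2.46), the spindle gene Ckap2 (3.68), Zmat3 (0.87) and Sesn1 (0.68). Camera adjusted p was 0.00194, 0.0001 and 0.000815 for these 3, lost with adjusted p = 0.337, 0.240 and 0.0826 with an estimated correlation. With library totals 16, 15 and 15 of their members rose and 0, 0 and 1 fell.

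**Figure D4:**
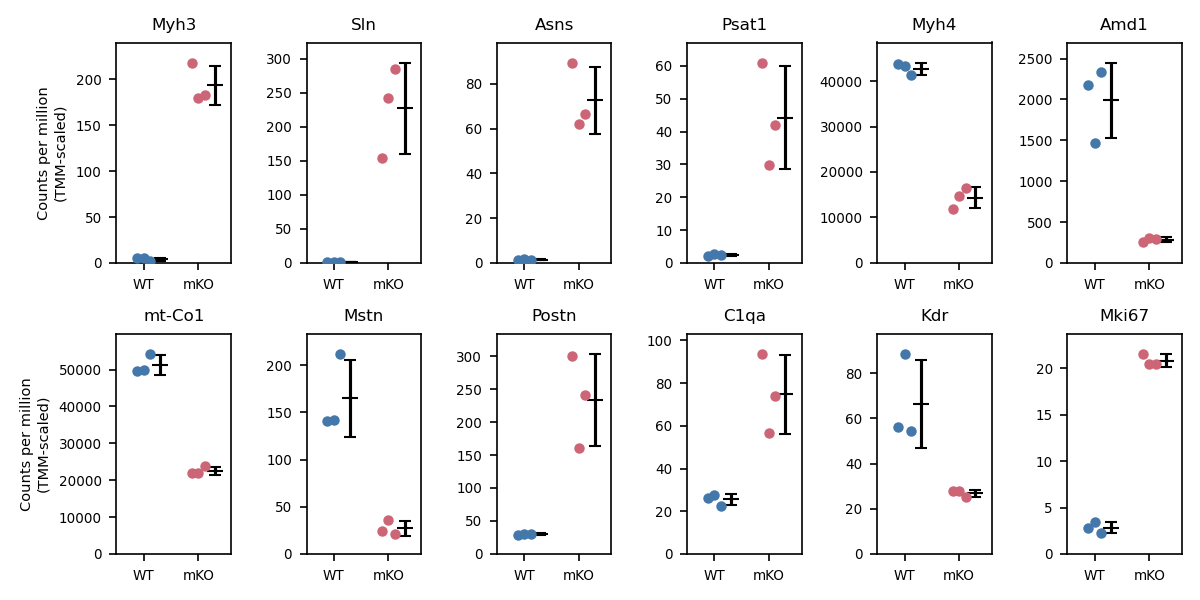
TMM-scaled CPM of 12 genes in each of 3 WT and 3 mKO libraries, with points for libraries and bars for mean and SD. The 12 genes were chosen after their values were seen to show the main groups, and in each the groups do not overlap.

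Growth and atrophy genes moved in both directions with TMM scaling, and camera called none of these 5 lists. With library totals 13 atrophy genes rose and 2 fell, as did 6 and 3 of the myokine list, 16 and 1 of the insulin list, 12 and 2 of the mTORC1 list and 10 and 0 of the autophagy list. Of 19 atrophy ligases and atrogenes, 6 rose and 5 fell (7 and 6 adjusted over the list alone). Camera adjusted p was 0.408 for this list, and the directional fry test gave 0.0101. The metallothionein gene Mt2 rose from 1.47 to 13.6 CPM and the proteasome subunit gene Psmd11 by log2 0.90, while Mstn, which encodes the growth inhibitor myostatin, fell from 165 ± 40.9 to 27.1 ± 8.04 CPM and Asb2 by log2 -1.01. The muscle ubiquitin ligase genes Trim63 and Fbxo32, singled out after their values were seen, fell by log2 values of -0.67 and -0.44; neither change held with library totals (log2 -0.21 and 0.02). Of 19 myokine and TGF-beta genes, 5 rose and 6 fell (the same adjusted over the list alone; camera adjusted p = 0.484). Gdf11, closely related to Mstn, fell (14.9 to 3.49 CPM), as did Fndc5 (log2 -0.94), and the stress hormone gene Fgf21 had 2 against 142 counts, a ratio of 55.0 (exact 95% counting interval 14.9 to 458). Of 24 insulin, IGF and Akt signalling genes, 7 rose and 5 fell (7 and 6 adjusted over the list alone; camera adjusted p = 0.660). Grb10, an adaptor that damps insulin signalling, rose (42.3 to 105 CPM), as did Irs2 (log2 0.69) and Igf1r (log2 0.70), and the glucose transporter gene Slc2a4 fell (273 to 143 CPM). In mTORC1 signalling 6 of 19 rose and 3 fell (7 and 6 adjusted over the list alone; camera adjusted p = 0.479), with Eif4ebp1 up (23.7 to 64.3 CPM), Sesn1 up (log2 0.68), and Ddit4l (log2 -1.11) and Rragd (log2 -0.79) down. In autophagy and lysosome 3 of 18 rose and 3 fell (the same adjusted over the list alone; camera adjusted p = 0.979). Ctsb (log2 0.72), Map1lc3b (0.48) and Wipi1 (0.44) rose and Atg12 (-0.71) fell; Wipi1 was not called without WT replicate 1 (edgeR adjusted p = 0.059), and Atg12 not with library totals (log2 -0.25).

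Dividing cells, matrix and immune genes were raised. Of 18 proliferation genes, 16 rose and none fell (17 adjusted over the list alone; camera adjusted p = 5.44e-11, and 0.0451 with an estimated correlation): Mki67 from 2.84 ± 0.588 to 20.8 ± 0.651 CPM, Top2a from 1.63 to 11.7 CPM, Ccna2 by log2 3.02 and Rrm2 by log2 2.10. Of 19 matrix and fibrosis genes, 14 rose and none fell (16 adjusted over the list alone; camera adjusted p = 1.35e-08, and 0.0451 with an estimated correlation). Postn, which encodes periostin, rose from 30.0 ± 1.06 to 234 ± 70.0 CPM, the protease inhibitor gene Timp1 11.3-fold, Bgn by log2 1.16 and Lox, which cross-links collagen, by log2 1.09. All 15 macrophage markers rose (also 15 adjusted over the list alone): Cd68 from 1.75 to 10.8 CPM, C1qb from 7.35 to 28.8 CPM, C1qa from 25.5 to 74.7 CPM and Trem2 from 0.445 to 4.68 CPM (camera adjusted p = 5.30e-14, lost with adjusted p = 0.187 with an estimated correlation). In the interferon response 15 of 20 rose and none fell (16 adjusted over the list alone), with Mx1 (log2 2.62), Oasl2 (2.33), Ifit3 (1.44) and Irf7 (2.47). Of 16 inflammatory signalling genes, 11 rose and none fell (the same adjusted over the list alone), with the receptor gene Tnfrsf12a (25.4 to 91.9 CPM), Socs3 (log2 2.14), the chemokine gene Ccl2 (2.35) and Stat3 (1.09). Camera adjusted p was 1.42e-06 and 9.27e-06 for these 2, lost with adjusted p = 0.119 and 0.113 with an estimated correlation.

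Markers of the other cells in whole muscle did not move together. Endothelial genes fell, 11 of 14 with none higher (the same adjusted over the list alone), such as Egfl7 (41.7 to 17.9 CPM), Aqp1 (154 to 72.9 CPM), Emcn (log2 -0.94) and Kdr, the receptor for VEGF (66.4 ± 19.3 to 26.8 ± 1.46 CPM); camera adjusted p was 2.14e-05, lost with adjusted p = 0.249 with an estimated correlation, and 4 fell and 1 rose with library totals. Red blood cell genes had 2 of 5 lower and none higher (the same adjusted over the list alone), Alas2 (log2 -1.47) and Hbb-bs (-1.67), a globin gene with near-identical copies. That list was called (camera adjusted p = 0.0471, lost with adjusted p = 0.250 with an estimated correlation) and was lost without WT replicate 2 (0.0611) or mKO replicate 2 (0.0673).

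Camera called none of the remaining cell type lists. With library totals 4 pericyte genes rose and 2 fell, as did 7 and 1 of the progenitor list, 3 and 0 of the satellite list, 5 and 0 of the tenocyte list, 1 and 1 of the adipocyte list, 2 and 1 of the lymphocyte list and 1 and 0 of the Schwann list, and Myh11, Smoc2, Col15a1, Spry1, Hey1, Calcr, Cnp and Fabp4 were no longer called. Pericyte and smooth muscle genes had 2 higher and 4 lower of 12 (2 and 5 adjusted over the list alone; camera adjusted p = 0.118, but 0.0226 without a low-count filter), with Rgs5 (581 to 258 CPM), Kcnj8 (log2 -1.22) and Myh11 (-0.59) lower and Acta2 (0.57) higher. Fibro-adipogenic progenitor genes had 1 higher and 3 lower of 14 (the same adjusted over the list alone; 0.539), with Hsd11b1 (-1.29), Smoc2 (-0.76) and Col15a1 (-0.50) lower and Mfap5 (0.94) higher. Satellite cell genes had 2 higher and 3 lower of 10 (3 and 3 adjusted over the list alone; 0.848), Spry1 (-0.64), Hey1 (-0.77) and Calcr (-1.39) lower and Vcam1 (0.67) higher. The call of Hey1 ended without WT replicate 1 (edgeR adjusted p = 0.109) or any 1 mKO replicate (0.0765, 0.0577, 0.0793), that of Calcr without WT replicate 3 (0.103), mKO replicate 1 (0.0766) or 2 (0.0590), and that of Vcam1 without WT replicate 1 (0.0745), mKO replicate 1 (0.105) or 3 (0.0529). Tenocyte genes had 2 higher and none lower of 10 (the same adjusted over the list alone; 0.308), Thbs4 (225 to 440 CPM) and Tnmd (0.44). Adipocyte genes had 2 lower and none higher of 12 (the same adjusted over the list alone; 0.408), Fabp4 (-0.73) and Scd1 (-1.20). Lymphocyte and neutrophil genes had 1 higher, Cd4 (1.74), and 1 lower, Mmp9 (-1.73), of 5 (the same adjusted over the list alone; 0.949). Schwann cell and nerve genes had 1 lower of 11, Cnp (-0.48), which was 0 adjusted over the list alone (0.670). The call of Tnmd ended without WT replicate 3 (0.0901), mKO replicate 2 (0.0737) or 3 (0.0836), that of Cd4 without WT replicate 2 (0.0981) or 3 (0.125) or mKO replicate 1 (0.122) or 2 (0.0689), and that of Cnp without WT replicate 3 (0.0659) or mKO replicate 1 (0.0704) or 2 (0.0768).

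Lists of RNA-binding and nuclear genes related to Hnrnpu were not called with TMM scaling. With library totals, 17 hnRNP genes rose and 1 fell, as did 12 and 1 of the SR and spliceosome list, 12 and 0 of the muscle splicing list and 14 and 0 of the nuclear matrix list. Of 24 hnRNP family genes, 5 rose and 5 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.930): Hnrnph1 (122 to 65.0 CPM), Hnrnpa2b1 (log2 -0.67) and Hnrnpdl (-0.56) fell and Pcbp1 (0.65) rose. Of 22 SR proteins and core spliceosome genes, 1 rose and 5 fell (the same adjusted over the list alone; 0.408): Snrpb fell from 49.5 to 19.9 CPM, Srsf6 by log2 -0.51, Srsf5 by -0.50 and Luc7l3 by -0.37. Of 19 muscle splicing regulators, 1 rose and 4 fell (the same adjusted over the list alone; 0.728): Mbnl1, a regulator of adult splicing, fell from 1043 to 619 CPM, Rbfox1 by log2 -0.53 and Srpk1 by -0.40, and Rbm20 rose by 0.39. Of 20 nuclear matrix, chromatin looping and noncoding RNA genes, 2 rose and 3 fell (2 and 2 adjusted over the list alone; 0.848): the lamin gene Lmna rose from 70.8 to 148 CPM and Nono by log2 0.57, and the noncoding RNA Malat1 fell by -0.56 and Lbr by -0.37. With library totals Hnrnpa2b1, Hnrnpdl, Srsf6, Srsf5, Mbnl1, Rbfox1 and Malat1 were no longer called, and Luc7l3, Srpk1 and Lbr turned to small positive values. The call of Luc7l3 ended without WT replicate 1 (edgeR adjusted p = 0.0507) or 3 (0.0881) or mKO replicate 1 (0.0683) or 3 (0.0676). That of Lbr ended without WT replicate 1 (0.0676) or 3 (0.0747) or mKO replicate 1 (0.0632) or 3 (0.114), and that of Nono without WT replicate 1 (0.0690) or 3 (0.0832) or mKO replicate 1 (0.0562). Of 18 circadian clock genes, 5 rose and 3 fell (the same adjusted over the list alone; 0.556; 14 and 1 with library totals), with Per2 (log2 1.24), Per1 (0.97) and Cry2 (0.94) higher and Hlf (-1.11) lower. Median, mean and camera direction differed in sign for the hnRNP, muscle splicing, nuclear matrix, insulin, autophagy and lymphocyte lists, none of which was called.

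Within 10 Mb of Hnrnpu, 88 of 188 tested genes changed, 46.8% against 37.0% of all tested genes. The largest changes in size there were Gm38251, an antisense gene with 72 counts in WT and 1 in mKO-labelled libraries, a ratio of 0.0108 (exact 95% counting interval 0.000269 to 0.0619), Fcgr4, a macrophage Fc receptor gene (log2 5.29), and the pseudogene Tma7-ps (-3.68), whose count is uncertain and whose call ended with robust dispersion (edgeR adjusted p = 0.0534). Next were Pld5, of the phospholipase D family (15.2 ± 0.968 to 1.36 ± 0.120 CPM, log2 -3.47), and Ly9, a lymphocyte surface receptor gene (log2 3.15). Their annotated starts on chromosome 1 are 184923136, 171018920, 171711088, 175962306 and 171588624.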

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

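The test on protein-coding genes alone was chosen after seeing the data; the other alternatives were planned before the data were examined. With library totals in place of TMM factors, 9283 genes were called, 8159 higher and 1124 lower, of which 4146 were shared with the 6166 called with TMM factors. Hnrnpu turned from a log2 change of -0.20 to 0.27 (edgeR adjusted p = 0.0402), and Srpk1, Luc7l3 and Lbr turned to 0.0703, 0.0921 and 0.0969. Scaling is the only choice that differs there, and it moves the median of all genes up. Stricter thresholds call fewer genes by construction: 3973 (1867 higher) at an adjusted p under 0.01, and 2050 (1144 higher and 906 lower) when tested against a fold of 1.5. Of 41 lists, camera called 21 with the preset correlation and 8 with an estimated correlation. The mixed fry test, which asks whether members changed in either direction rather than more than other genes, called 39. The directional fry test called 25, of which 20 were among the 21, without the slow-fibre list (adjusted p = 0.111). Its other calls were the neuromuscular junction (0.00756), dystrophin (0.000397), sarcomere (0.0131), pericyte (0.00756) and atrophy (0.0101) lists.

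Apart from leave-one-out and block fits, the other planned settings gave 5682 to 7459 changed genes, among them 6027 with DESeq2, 6213 with limma-voom and 6571 without a low-count filter, and protein-coding genes alone gave 5564. No gene called with the main settings was called in the opposite direction under another. Leave-one-out fits gave 4766 to 6255 changed genes, 2350 to 3065 higher and 2416 to 3190 lower, 19 to 22 lists, and a log2 change of Hnrnpu from -0.22 to -0.18. The fit with the replicate block gave 5519 changed genes, 5439 of them shared, 22 lists and -0.20 for Hnrnpu. Deviations of same-numbered libraries correlated at 0.0185, -0.00202 and 0.0224, within the range of differently numbered ones (-0.0577 to 0.0347). No strong shared deviation was seen, but this cannot exclude that same-numbered mice were related or handled together. Of 172 named genes called, 127 kept their call and direction under every one of 20 settings in which they were tested; the test against a fold of 1.5 ended 44 calls, library totals ended 16 and turned 3, and an adjusted p under 0.01 ended 11. Exon usage and its alternatives were not run on gene counts. In simulated data of this depth and spread with 200 changed genes, 40% of 1.5-fold changes were recovered. That share does not carry over to the real comparison, where many more genes were called, but the absence of a call does not exclude small changes.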

Other observations

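The gene families here, and all tests below except those of the splits, the 10 Mb window, gene span and the 3 noncoding classes, were chosen after the values were seen. Families were matched by symbol, so some also hold pseudogenes, such as Tubb4b-ps1, Hist3h2bb-ps and Ifi203-ps. Of 9 families, 6 were called higher and 2 lower with the preset correlation, and none with an estimated one. Of 17 cytosolic aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, 10 rose and 1 fell, with Gars at log2 1.27, Mars at 1.16 and Cars at -0.82 (camera adjusted p = 0.000271, lost with adjusted p = 0.166 with an estimated correlation). Of 50 replication-dependent histone genes, 26 rose and 5 fell, with Hist2h2be at 1.75 and Hist1h1a at 1.97, and of 14 tubulin genes 7 rose and none fell, with Tubb6 at 1.97 and Tuba1c at 2.39 (2.50e-05 and 0.000271; 0.166 and 0.300 with an estimated correlation). Of 8 MHC class II genes 6 rose and none fell, such as H2-Aa (1.57) and H2-Ab1 (1.53); of 19 chemokine genes 10 rose and 2 fell, such as Ccl8 (3.76); and of 12 Ifi200 genes 9 rose and none fell, such as Ifi209 (2.04). Their camera adjusted p was 2.26e-05, 0.000247 and 0.000157, lost with adjusted p = 0.166, 0.166 and 0.220 with an estimated correlation. Similar members of these families share reads, so single genes are uncertain. Overlap of the families with the 10 Mb window around Hnrnpu was not counted. The Ifi200 calls may therefore not be separate from the calls in that window.

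Of 78 mitochondrial ribosomal protein genes 31 fell and 2 rose, with Mrpl54 at log2 -1.45 and Mrpl39 at -0.97 (camera adjusted p = 2.50e-05, lost with adjusted p = 0.383 with an estimated correlation), and with library totals 24 rose and 9 fell, with a median of 0.20 against -0.26. Of 44 genes with potassium channel symbols 14 fell and 8 rose (0.00645, lost with adjusted p = 0.166 with an estimated correlation), and with library totals 11 rose and 10 fell, with a median of 0.17 against -0.29. The 44 include Kcnq1ot1, a noncoding RNA gene and not a channel gene, which was not called (log2 0.19, edgeR adjusted p = 0.229). Camera put both families lower relative to other genes under either scaling. Of 81 cytosolic ribosomal protein genes 8 fell and 1 rose, without a call (0.220), and with library totals 52 rose and 2 fell.

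The count of Hnrnpu in the mKO-labelled libraries was 87.2% of WT, although its deletion in muscle is in the labels. Whether scaling hides a loss stays open: with library totals the log2 change was 0.27, but that setting moves all genes up alike. An exchange of 1 library between groups is argued against, since the lowest correlation within groups exceeded the highest between groups by 0.0313. Reads from exons outside a deleted part and from cells other than fibres may keep the count up, and the 87.2% cannot be told apart from either, because gene counts do not show which exons the reads came from. Labels turned around as a whole were not tested.

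Macrophage genes rose while fast-fibre genes fell. A lower share of fibre RNA alone would raise markers of all other cells alike, yet the macrophage median exceeded the endothelial one by 2.23 on the log2 scale. The endothelial list was itself lower. This gap therefore cannot exclude a lower fibre share beside a separate fall of endothelial genes. The fibro-adipogenic progenitor median was -0.10. Bootstrap intervals were 1.26 to 1.97 for macrophage, -0.90 to -0.54 for endothelial and -0.31 to 0.22 for fibro-adipogenic progenitor genes. They resample the marker genes of each list as if independent, not the libraries, so they do not measure spread between mice. Estimated correlations within these lists were 0.69, 0.38 and 0.37, which makes the intervals too narrow. Scaling is argued against as the whole cause, since with library totals the fast-fibre median was still -0.63. More macrophages in the tissue and a change of expression within cells both stay open, and neither was tested.

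Genes near Hnrnpu changed more often than elsewhere in a 10 Mb window: 46.8% of 188, above the 95th percentile of 1199 other windows (44.1%). Within 4 Mb the share was 36.6% of 71 genes, under the 95th percentile of windows of that size (47.9%). The narrower window leaves out immune gene clusters, which a candidate explanation names as the source of the excess. It was set after the values were seen and also drops every other gene between 4 and 10 Mb. The share within 10 Mb without immune genes was not computed, so the lower share does not decide on that source. A segment of 129 origin around the targeted allele cannot be told apart from immune gene clusters, as strain variants were not read.

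The 6 libraries make 10 splits into 2 groups of 3, so a share under 0.05 cannot be reached: 1 of 10, the real one, gave 6166 genes, and the highest of the others gave 0. Fold change and gene span correlated at -0.0322 (Spearman), within the range of the other splits (-0.0646 to 0.0741). Those splits mix WT and mKO-labelled libraries and are too few to set a 0.05 limit, so the range does not decide. The correlation itself was small. Among protein-coding genes the median log2 change was -0.03 in the fifth with the shortest span and -0.02 in the longest, so no joint shift of long genes was seen. The 1331 genes of 3 noncoding classes (TEC, sense intronic and antisense) had a median log2 change of 0.26, against 0.24 for expression-matched protein-coding draws (upper limit 0.29), so whether intronic or read-through RNA adds to them cannot be told apart. By contrast, 66 snoRNA genes had a median of -0.67 (1 higher, 26 lower) against 0.22 for matched draws (limits -0.0193 and 0.479), and 430 lincRNA genes a median of 0.38 (122 higher, 60 lower) against 0.20 (limits 0.11 and 0.29). The share of structural RNAs and protein-coding counts also differed between groups, and the cause was not tested.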
